A study of Mus musculus with 21 samples.

How the data were processed

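E14 mouse embryonic stem cells were profiled with 1, 2 or 3 barcoded antibodies, from 100000 cells per bulk sample with 17 PCR cycles. The series holds 21 samples in 11 groups. Region lists were available for H3K27ac alone, RNAPII alone and the 3 dual-antibody groups, and a peak list for ATAC, each with 2 samples per group. H3K27me3 alone, H3K27me3 with IgG, RNAPII with IgG, the triple-antibody group and the single-cell sample have no region list and were not analysed here, so no control library could be set beside the values.

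Per the submitters' processing notes, Bowtie2, Picard and HOMER were used with the mm10 build, and no versions are given. Per the file headers, the authors called single-antibody regions per sample with HOMER findPeaks in its histone style without a control library, at a Poisson p of 0.001, with a peak size of 500 bp and stitching within 1000 bp, and the signal of a region is its number of tags per 10000000 tags. Per the file headers, the ATAC peaks were called on a combined tag directory of 105078485.5 tags in the factor style, with an FDR of 0.001 and at least 4-fold over the local 10000 bp. The deposited dual-antibody lists were merged by the authors with HOMER mergePeaks from 2 replicate lists each, and the headers do not say how those were called. Their deposited signal values step by a fixed unit, as tag counts in steps of 0.5 per 10000000 tags would, and how the values of 2 replicates were combined is not stated. The 2 parent columns of each merged list show which replicate list held a region, and these were used as the replicates. Regions held by both kept the same merged coordinates and value in each. The SD between dual replicate lists can therefore understate the replicate spread. The signal values are the authors' own and were compared only within a list. The headers of the single H3K27ac lists name tag directories numbered the other way round from the labels, and the labels were used.

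Depth was taken from the headers for single lists and ATAC. For dual lists it was read from the step of the values and is given to 4 digits. Among the antibody lists it ranged from 195700 tags in a mixed replicate of the H3K27ac/RNAPII experiment to 8249139 tags in RNAPII replicate 2. Tags come from PCR libraries without molecular identifiers, so any precision from depth covers counting error only. Regions were taken as deposited, without a further filter, on the autosomes and X.

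Overlap was counted as at least 1 bp. For each of 182 ordered pairs among 14 lists, the share of overlapped regions was set against 100 random placements of the first list on its own chromosomes (seed 20240), and p is the one-sided share of placements with at least as much overlap, with the real one included. The lowest possible p is 0.0099, so with 178 of 182 pairs at that value a Benjamini-Hochberg adjustment leaves them below 0.05. The planned window around transcription starts was replaced, since the gene table gives no strand: a region counted for a gene when it lay within 1 kb of either end. Of 287 genes in 11 lists, 287 were found in the gene table, which is on GRCm38.p6, the assembly of mm10, and holds 21631 protein-coding genes. The percentile of each list was taken among 10000 random lists of the same size and gene types. Genes are not replicates, so no p was computed across genes. Named genes followed a rule fixed before the data were examined: a panel of 24 genes, the 10 genes with the highest mixed region in each mixed list, and up to 4 members of each gene list with the highest values. The gene lists, comparisons and most alternatives were fixed at the same time.

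For each H3K27me3 list, regions were sorted into deciles by value within a replicate list, and the 500 bp around the centre was tested for overlap, over all regions and outside the single lists of the other target. The overlap step was tested on simulated data made from 20594 placed regions of the H3K27ac/RNAPII mixed list against the H3K27ac list of the H3K27ac/H3K27me3 experiment: planted shares of 20.1% and 49.98% were recovered as 20.05% and 50.03%, and a planted share of 0 gave a fold of 1.01. Alternatives tried were a 50% overlap, the higher-scoring part of each list, the 10000 highest-scoring regions, circular shifts, all chromosomes, draws of ATAC peaks, wider windows, single replicates, and regions in both replicate lists. Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and Matplotlib 3.10.9 were used.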

Results

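Multi-CUT&Tag was used in E14 mouse embryonic stem cells to map 3 chromatin targets, alone and in pairs. Each antibody was bound to protein A-Tn5 transposase with its own barcode, which records the antibody that directed a cut. H3K27ac is a histone mark of active promoters and enhancers, H3K27me3 is the mark laid down by Polycomb repressive complexes, and the RNAPII antibody recognised Rpb1 phosphorylated at serine 2, the form found on elongating polymerase. Region lists were deposited for 5 of the 11 groups of samples and a list of open sites from ATAC, an assay of accessible DNA, for a further group. H3K27ac alone and RNAPII alone were each represented by 2 replicate lists. The 3 dual-antibody experiments (H3K27ac/H3K27me3, H3K27ac/RNAPII and RNAPII/H3K27me3) each gave a list for the first target, a list for the second and a mixed list, and each of these was merged by the authors from 2 replicate lists. The labels do not say whether replicates came from separate cultures, so their spread can be technical alone.

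Depth differed widely between lists. The single-antibody lists rested on 1231070 and 6565665 tags for H3K27ac and on 5604000 and 8249139 tags for RNAPII. Depth was highest among the dual lists for RNAPII in the RNAPII/H3K27me3 experiment, at 4481000 and 5682000 tags in the 2 replicates. The H3K27ac list of the H3K27ac/H3K27me3 experiment rested on 1586000 and 2546000 tags. The H3K27ac/RNAPII experiment was the shallowest, with 639200 and 261000 tags for H3K27ac, 892900 and 587700 for RNAPII, and 433700 and 195700 for the mixed class. H3K27me3 rested on 1953000 and 3078000 tags beside H3K27ac and on 2917000 and 3940000 tags beside RNAPII. A region missing from a list is one that the authors' caller did not pass at that depth. Mixed fragments made up 20.7% ± 0.123 of the tags in the H3K27ac/H3K27me3 experiment, 20.4% ± 2.35 in the H3K27ac/RNAPII experiment and 20.4% ± 0.633 in the RNAPII/H3K27me3 experiment (SD, n = 2 libraries each).

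The first comparison asked how far replicate lists of a single target overlapped. H3K27ac regions of replicate 1 were covered by replicate 2 in 91.3% of cases, and those of replicate 2 by replicate 1 in 33.3%. RNAPII regions of replicate 1 were covered by replicate 2 in 84.6% of cases, and those of replicate 2 by replicate 1 in 68.6%. The deeper replicate held more regions for H3K27ac (84137 against 36232) and for RNAPII (93027 against 86588). The share for replicate 1 was 11.8-fold higher for H3K27ac and 7.68-fold higher for RNAPII than when its regions were placed at random (permutation, one-sided, p = 0.0099, the smallest that 100 placements can give). With the 10000 highest-scoring regions of each list these folds were 33.5 and 16.2.

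The second comparison asked how far the regions of a target beside a second antibody and alone overlapped. H3K27ac regions of the H3K27ac/RNAPII experiment lay in single-antibody H3K27ac regions in 72.8% ± 17.6 of cases (SD over 2 single lists, n = 2), 16.9-fold above random placement. H3K27ac regions of the H3K27ac/H3K27me3 experiment did so in 50.9% ± 23.5 of cases (n = 2), 10.2-fold above random. RNAPII regions lay in single-antibody RNAPII regions in 88.5% ± 2.96 of cases beside H3K27ac and in 66.8% ± 3.31 beside H3K27me3 (n = 2 each), 9.45-fold and 6.67-fold above random. For H3K27ac in both experiments the fold was higher in the lists of its own target than in RNAPII lists, where it was 7.79 beside RNAPII (SD 0.782 against 7.32) and 6.77 beside H3K27me3 (SD 0.616 against 2.00). These SDs are between single lists of unlike size and do not measure the spread of the dual experiments. In the larger H3K27ac list, of replicate 2, the folds were 11.7 beside RNAPII and 8.79 beside H3K27me3. In the 2 RNAPII lists they were 8.34 and 7.23 beside RNAPII, and 7.205 and 6.33 beside H3K27me3. The share of H3K27ac regions beside H3K27me3 that lay in RNAPII lists was nevertheless the higher one, at 62.3% ± 2.15 against 50.9%, and beside RNAPII it was 69.4% ± 2.19 against 72.8%. RNAPII regions of the RNAPII/H3K27me3 experiment were 6.03-fold above random in H3K27ac lists, a difference from the fold in RNAPII lists that lay within the spread (SD 0.778 and 0.450, n = 2). RNAPII regions of the H3K27ac/RNAPII experiment were 11.2-fold above random in H3K27ac lists, higher than in RNAPII lists but within the spread as well (SD 3.24, n = 2). The folds in the 2 H3K27ac lists were 13.5 and 8.90. The shares of these regions were in the other order, at 53.9% ± 20.45 in H3K27ac lists against 88.5% in RNAPII lists. In the other direction, the 2 single H3K27ac lists lay in H3K27ac regions beside H3K27me3 in 72.4% and 53.0% of cases and in those beside RNAPII in 40.9% and 22.0%. The 2 single RNAPII lists lay in RNAPII regions beside H3K27me3 in 74.2% and 65.6% of cases and in those beside H3K27ac, a shallower list, in 31.05% and 27.1%. H3K27me3 regions lay in single H3K27ac regions in 11.8% ± 6.60 of cases beside H3K27ac and in 9.85% ± 6.54 beside RNAPII (n = 2 each), 1.91-fold and 1.48-fold above random. Each single pair was at p = 0.0099 (permutation, one-sided), the smallest possible, and the 10000 highest-scoring regions gave folds in their own target of 12.1 to 40.4. With 2 lists a side the smallest 2-sided p of an exact test between experiments is 0.333, so values and spreads are given.

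**Figure D1:**
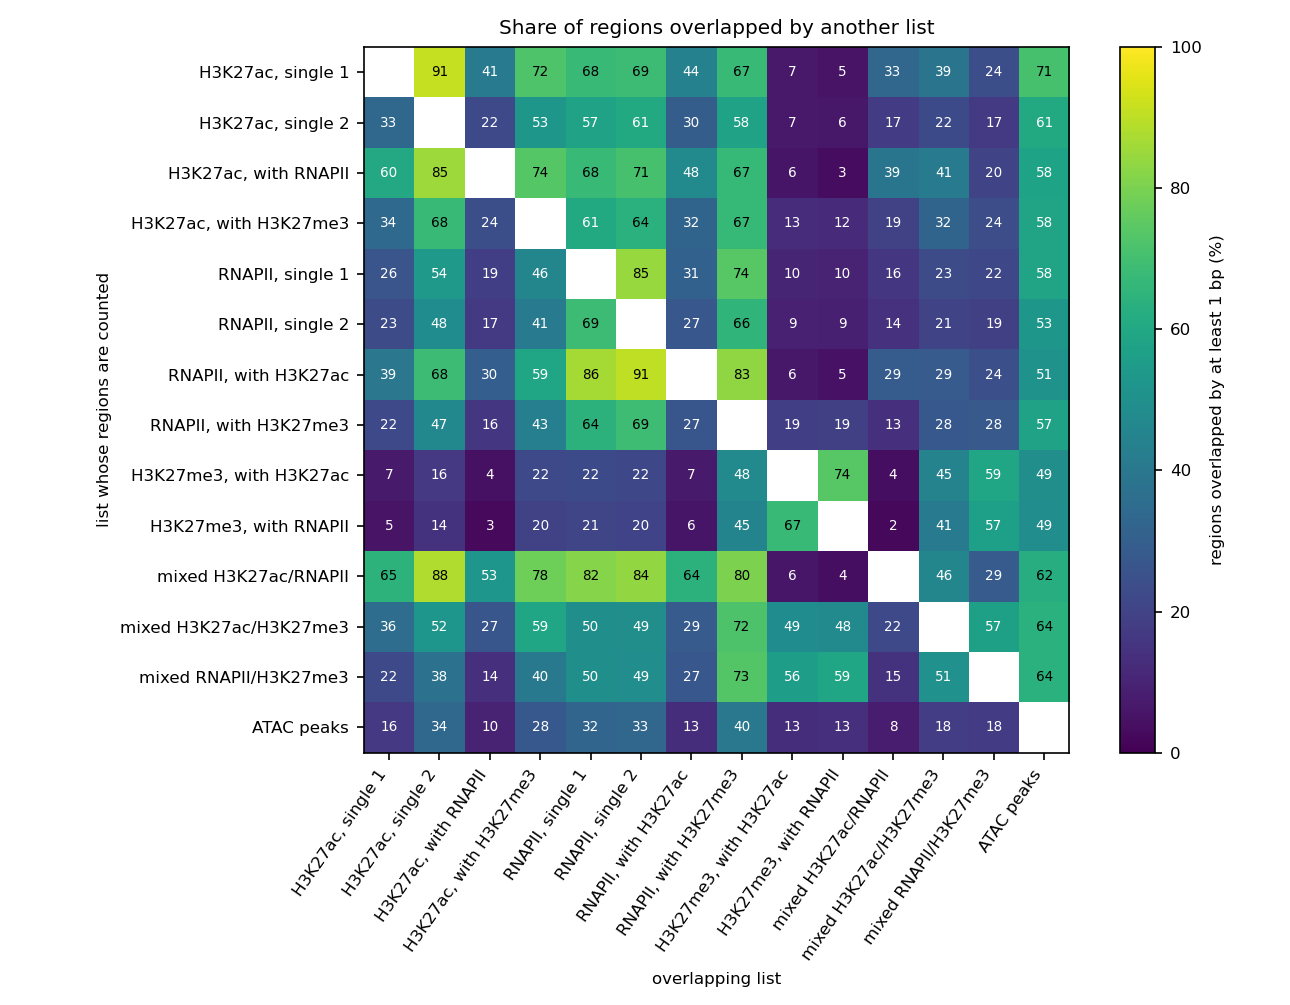
Share of the regions of each list (vertical axis) that another list (horizontal axis) overlaps by at least 1 bp, in percent. Single replicate 2 covers 91.3% of the H3K27ac regions of replicate 1, and the 2 H3K27me3 lists cover 74.1% and 67.2% of each other.

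The third comparison set the lists of a target in 2 dual experiments against each other. H3K27me3 was alike in both: 74.1% of its regions beside H3K27ac were found beside RNAPII (16.2-fold above random) and 67.2% in the other direction (15.1-fold). The widest H3K27me3 region of the RNAPII/H3K27me3 experiment spanned 134.0 kb over the Hoxc cluster on chromosome 15 (102908665 to 103042694, mm10). Beside H3K27ac the widest H3K27me3 region spanned 79.3 kb. H3K27ac regions beside RNAPII were found beside H3K27me3 in 73.7% of cases (13.5-fold), with 24.0% in the other direction. RNAPII regions beside H3K27ac were found beside H3K27me3 in 83.4% of cases (8.44-fold), with 26.8% in the other direction. All 6 directions were at p = 0.0099 (permutation, one-sided), the smallest possible. The 10000 highest-scoring regions gave 37.0-fold for H3K27ac, 25.9-fold for H3K27me3 and 18.7-fold for RNAPII.

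Beside H3K27me3, both other targets were found more often at H3K27me3 sites mapped in the other experiment. H3K27ac regions of the H3K27ac/H3K27me3 experiment lay in H3K27me3 regions of the RNAPII/H3K27me3 experiment in 11.9% ± 0.178 of cases (SD over 2 replicate lists, n = 2). The same share was 3.34% ± 0.0383 for H3K27ac of the H3K27ac/RNAPII experiment and 5.75% ± 0.789 for the single-antibody lists (n = 2 each). RNAPII regions of the RNAPII/H3K27me3 experiment lay in H3K27me3 regions of the H3K27ac/H3K27me3 experiment in 20.3% ± 0.0896 of cases, against 6.74% ± 0.151 beside H3K27ac and 9.68% ± 0.810 alone (n = 2 each). Both differences were larger than the spread between replicate lists. For the dual experiments this spread can be too small, since regions found in both replicate lists have the same merged coordinates.

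The mixed lists, taken from their name as fragments with the barcodes of both antibodies, were compared with the 2 target lists of their own experiment. In the H3K27ac/H3K27me3 experiment 16.8% of mixed regions lay in both targets' regions, 42.0% in H3K27ac regions only, 31.7% in H3K27me3 regions only and 9.51% in neither. In the H3K27ac/RNAPII experiment 39.7% lay in both, and in the RNAPII/H3K27me3 experiment 37.7%. Mixed regions of a single replicate list lay in both merged target lists more often, at 23.0% ± 6.46, 52.3% ± 15.9 and 46.5% ± 7.79 in the order named (SD, n = 2 each). The target lists were not cut to that replicate. Sites of both targets carried mixed regions most often: of the H3K27ac regions that overlapped H3K27me3, 90.1% overlapped a mixed region, against 23.6% of the other H3K27ac regions. The same shares were 90.7% and 13.4% for RNAPII regions with and without H3K27me3, and 62.8% and 17.1% for H3K27ac regions with and without RNAPII. Overlap of mixed regions with both targets was 23.1-fold, 43.6-fold and 16.0-fold above random placement in the order named (permutation, one-sided, p = 0.0099, the smallest possible). Set against draws of ATAC peaks in place of random positions, the folds were 4.11, 7.79 and 4.10. Without the first replicate list of the H3K27ac/RNAPII experiment, its fold was 87.2.

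The strongest mixed regions were named by the genes at whose ends they lay. In the H3K27ac/H3K27me3 experiment the highest value was at Cbx8, which encodes a Polycomb protein (chromosome 11, 119034132 to 119063677, mm10; 6696 tags per 10000000). It was followed by Irx4, a homeobox gene of the heart ventricle (4492), Tbx1, a T-box gene of the pharyngeal arches (4296), Skor1 (3703), the midbrain homeobox gene En1 (3695), a region shared by Ehbp1 and the forebrain gene Otx1 (3645), Sox6 (3533), Rtn4rl2 (3467) and Ankrd63 (3454). In the RNAPII/H3K27me3 experiment Cbx8 was again first (9282), followed by a region shared by Gm2102 and the neural crest gene Pax3 (8543), Dmrta2 (8475), a region shared by Gp1bb and Septin5 (7792), En1 (7677), Scarf2 (7669), Nkx1-1 (7502) and Wnt10a (7487). In the H3K27ac/RNAPII experiment the highest mixed region lay over the overlapping ends of the bromodomain gene Brd2 and H2-DMa (chromosome 17, 34119150 to 34122941; 3366). It was followed by regions at Cox20 and Hnrnpu (2107), Ewsr1 and Rhbdd3 (1953), the ribosomal protein gene Rps15a (1780), the heat shock gene Hspa8 (1415), and Gapdh and Ncapd2 (1372). Each of these regions was present in both replicate lists except the one at Gapdh and Ncapd2.

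Open chromatin was compared with every list. H3K27ac regions of single replicate 1 lay in ATAC peaks most often, in 71.0% of cases (8.56-fold above random), and H3K27me3 regions of the RNAPII/H3K27me3 experiment least often, in 48.9% (3.97-fold). The other H3K27me3 list stood at 49.4% (4.27-fold). Mixed regions stood at 62.2% to 63.9%, the other H3K27ac lists at 57.9% to 60.7% and RNAPII regions at 50.9% to 58.4%. The highest fold was 8.88, for mixed H3K27ac/RNAPII regions. All 13 lists were above random placement (permutation, one-sided, p = 0.0099, the smallest possible). The ATAC peaks are 110 bp wide, so that a rule asking for 50% of a region to be covered left 7 of these results at a fold of 0 and 3 more at p of 0.059 to 0.15 (permutation, one-sided).

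The H3K27me3 lists had the largest share of wide regions. Of their regions, 7.81% beside H3K27ac and 9.23% beside RNAPII were wider than 5 kb, and these held 42.3% and 46.4% of all covered bases. For H3K27ac the share wider than 5 kb was 0.316% beside RNAPII, 1.44% beside H3K27me3, and 1.39% and 2.92% in the single lists. For RNAPII it was 1.19% beside H3K27ac, 3.79% beside H3K27me3, and 4.50% and 6.27% in the single lists, where the widest regions of 130.2 kb and 105.9 kb exceeded the 79.3 kb of H3K27me3 beside H3K27ac. Among the antibody lists, regions within 1 kb of either end of a protein-coding gene were most frequent in the mixed RNAPII/H3K27me3 list (32.3%). Of the same lists, they were least frequent in H3K27ac of single replicate 2 (16.0%). H3K27me3 regions lay outside protein-coding genes and these windows in 44.2% and 45.2% of cases and RNAPII regions in 15.0% to 22.9%. In the higher-scoring part of the H3K27me3 list beside H3K27ac the share at gene ends was 32.0%, against 21.3% in the whole list.

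The gene lists were chosen before the data were examined, and the share of each list's genes with a region at a gene end was compared between experiments. Hox genes, which pattern the body axis, and regulators of cell fate such as Gata6, Pax6 and Foxa2 are known Polycomb targets in these cells, and all 79 carried H3K27me3 in every replicate list. H3K27ac was found at 67.7% ± 4.48 of these 79 genes beside H3K27me3, at 1.90% ± 2.69 beside RNAPII (3.80% and 0% in its replicates) and at 5.06% ± 5.37 in the single lists (1.27% and 8.86%; SD, n = 2 each). For the 39 Hox genes alone the shares were 53.9% ± 7.25, 1.28% ± 1.81 and 0%. RNAPII was found at 100% of the 79 genes beside H3K27me3, at 2.53% beside H3K27ac in both replicates, and at 44.9% ± 2.69 in the single lists (n = 2 each). Both differences from the single lists were larger than the spread between replicate lists, though those of a dual experiment share merged regions. H3K27ac beside H3K27me3 stood at 73.0% ± 3.48 of the 61 genes with an ATAC peak at an end and at 50% ± 7.86 of the 18 without (n = 2), and RNAPII at 100% of both. Values at these genes were moderate for H3K27ac and high for H3K27me3: the median rank of the best region within its own list was 69.4% for H3K27ac beside H3K27me3, 58.8% over 7 genes for H3K27ac of single replicate 2, 95.1% for RNAPII beside H3K27me3, 42.7% and 43.4% for the single RNAPII lists, and 99.8% and 99.7% for H3K27me3. With the 10000 highest-scoring regions of each list the H3K27ac share beside H3K27me3 fell to 12.0%, while RNAPII stood at 81.0% beside H3K27me3 and at 1.27% in the single lists. The H3K27ac/RNAPII lists were the shallowest, and their RNAPII share was 5.06% in a window of 2.5 kb, 6.96% over whole genes and 0% in the 10000 highest-scoring regions.

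Over all protein-coding genes H3K27ac stood at 50.6% ± 2.57 beside H3K27me3, 15.8% ± 6.52 beside RNAPII and 44.7% ± 11.8 alone, and RNAPII at 70.2% ± 0.451 beside H3K27me3, 32.2% ± 1.14 beside H3K27ac and 61.3% ± 0.451 alone (SD, n = 2 each). Several other gene groups were compared in the same way. Genes of primed pluripotency such as Otx2, Zic2 and Sox3 carried H3K27me3 in 100% of cases in both experiments, and H3K27ac in 81.8% beside H3K27me3, 9.09% beside RNAPII and 50% ± 6.43 in the single lists (n = 2 each). Germline genes such as Dazl, Sycp3 and Dmc1 carried H3K27me3 in 82.5% ± 10.6 and 87.5% ± 3.54 of cases, and RNAPII in 90.0% beside H3K27me3, 5.00% beside H3K27ac and 47.5% ± 3.54 alone. Trophoblast genes such as Cdx2, Eomes and Hand1 carried H3K27me3 in 67.5% ± 3.54 of cases in both experiments, and H3K27ac in 60% ± 14.1 beside H3K27me3, 10.0% ± 7.07 beside RNAPII and 35.0% ± 28.3 alone, so that its difference from the single lists was within their spread. Fibroblast genes carried H3K27me3 in 52.5% and 55.0% of cases and imprinted genes in 58.7% and 63.0%. Genes of differentiated tissues carried H3K27ac in 11.7% of cases both beside H3K27me3 and in the single lists. Alb, the serum albumin gene, had no region in any list.

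Most pluripotency and housekeeping genes had H3K27ac and RNAPII at an end in each experiment, though beside RNAPII Klf4 had no H3K27ac region and Esrrb none at its ends. H3K27ac stood at 95.2% ± 2.28 of 31 pluripotency genes beside H3K27me3, 61.3% ± 13.7 beside RNAPII and 96.8% ± 4.56 alone (SD, n = 2 each). RNAPII stood at 100% of them beside H3K27me3, 75.8% ± 2.28 beside H3K27ac and 98.4% ± 2.28 alone. H3K27ac was strongest beside H3K27me3 at Dppa5a, Klf2, Pou5f1 and Fgf4, where the values were 2542, 2085, 1749 and 1604 tags per 10000000. At Pou5f1, which encodes the pluripotency factor Oct4, this region ran from 35500608 to 35510550 on chromosome 17 (mm10). H3K27me3 was found at 11.7% ± 2.36 of 30 housekeeping genes beside H3K27ac and at 8.33% ± 2.36 beside RNAPII, and at 3.33% of them in the 10000 highest-scoring regions of each list. Mixed H3K27ac/H3K27me3 regions were found at 75.0% ± 11.8 of the same genes and mixed RNAPII/H3K27me3 regions at 78.3% ± 16.5. These shares were 48.3% and 55.0% with the 10000 highest-scoring regions. Genes for Polycomb and other chromatin proteins such as Ezh2 and Suz12 resembled housekeeping genes, with H3K27ac at 91.3% beside H3K27me3 and in the single lists, and H3K27me3 at 10.9% and 13.0%.

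**Figure D2:**
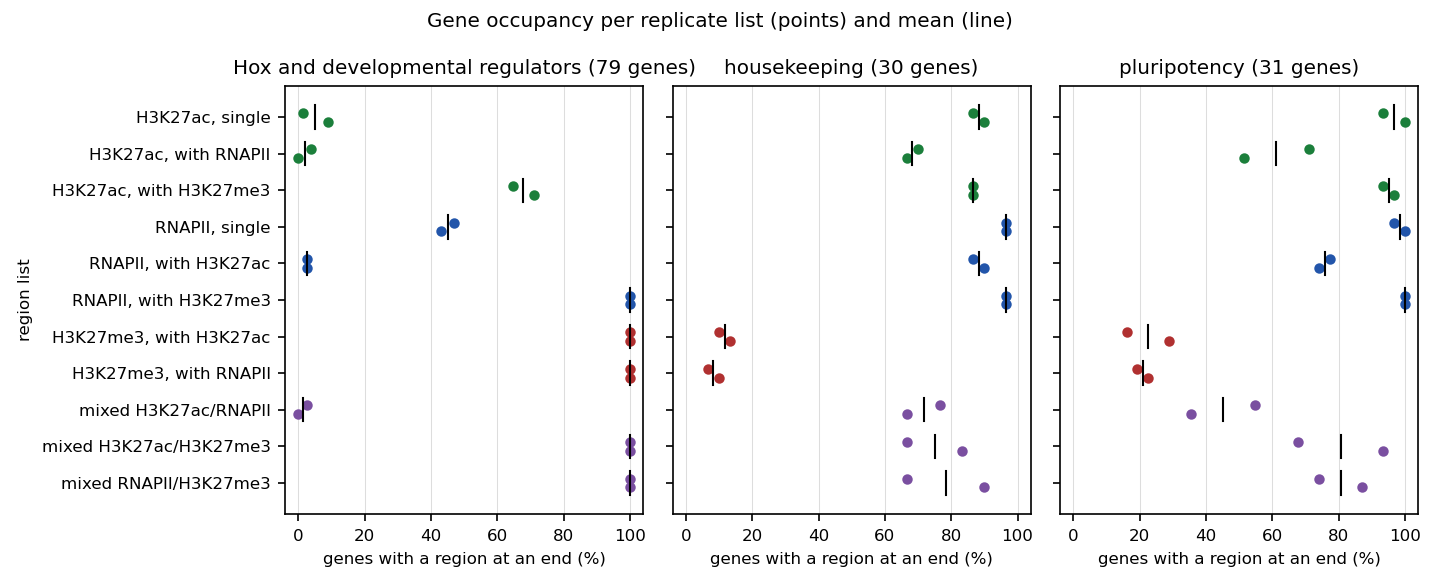
Share of the genes of 3 groups (percent, horizontal axis) with a region within 1 kb of a gene end in each kind of list (vertical axis), where points are replicate lists and lines their mean. H3K27ac stands at 67.7% of the 79 Hox and developmental regulator genes beside H3K27me3 and at 5.06% alone.

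Single loci showed the contrast between the lists. At Hoxa9 (chromosome 6, 52223097 to 52227370, mm10) neither single H3K27ac list had a region, and the H3K27ac list beside H3K27me3 had one of 1.06 kb at an end, with a value of 53.0 tags per 10000000 and found in 1 of its replicates, and another of 0.5 kb inside the gene. H3K27me3 covered Hoxa9 with regions of 43.1 kb and 66.4 kb, with values of 4748 and 5636. In a window around the Hoxa cluster (52140367 to 52275880) the RNAPII list beside H3K27me3 held 30 regions, against 6 and 3 in the single RNAPII lists. Some of the 30 lay beyond the outer Hoxa genes, and none of the single-list regions did. Gata6, a regulator of endoderm, carried an H3K27ac region of 3.48 kb with a value of 142.9 beside H3K27me3 and only a 0.5 kb region at its other end in 1 single list. Nkx2-2 and Foxa2 carried H3K27ac beside H3K27me3 and no region at their ends in any single list. Both Gata4, a heart and endoderm regulator, and the mesoderm gene T carried H3K27me3 in both experiments and RNAPII beside it at their ends, where no list had H3K27ac, and Gata4 had 4 H3K27ac regions inside the gene beside H3K27me3. Sox2, Nanog, Actb, Gapdh, Eef1a1 and Npm1 carried H3K27ac at an end in every H3K27ac list and no H3K27me3. Pou5f1 had a 0.5 kb H3K27me3 region with a value of 16.2 at an end in 1 replicate beside H3K27ac.

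**Figure D3:**
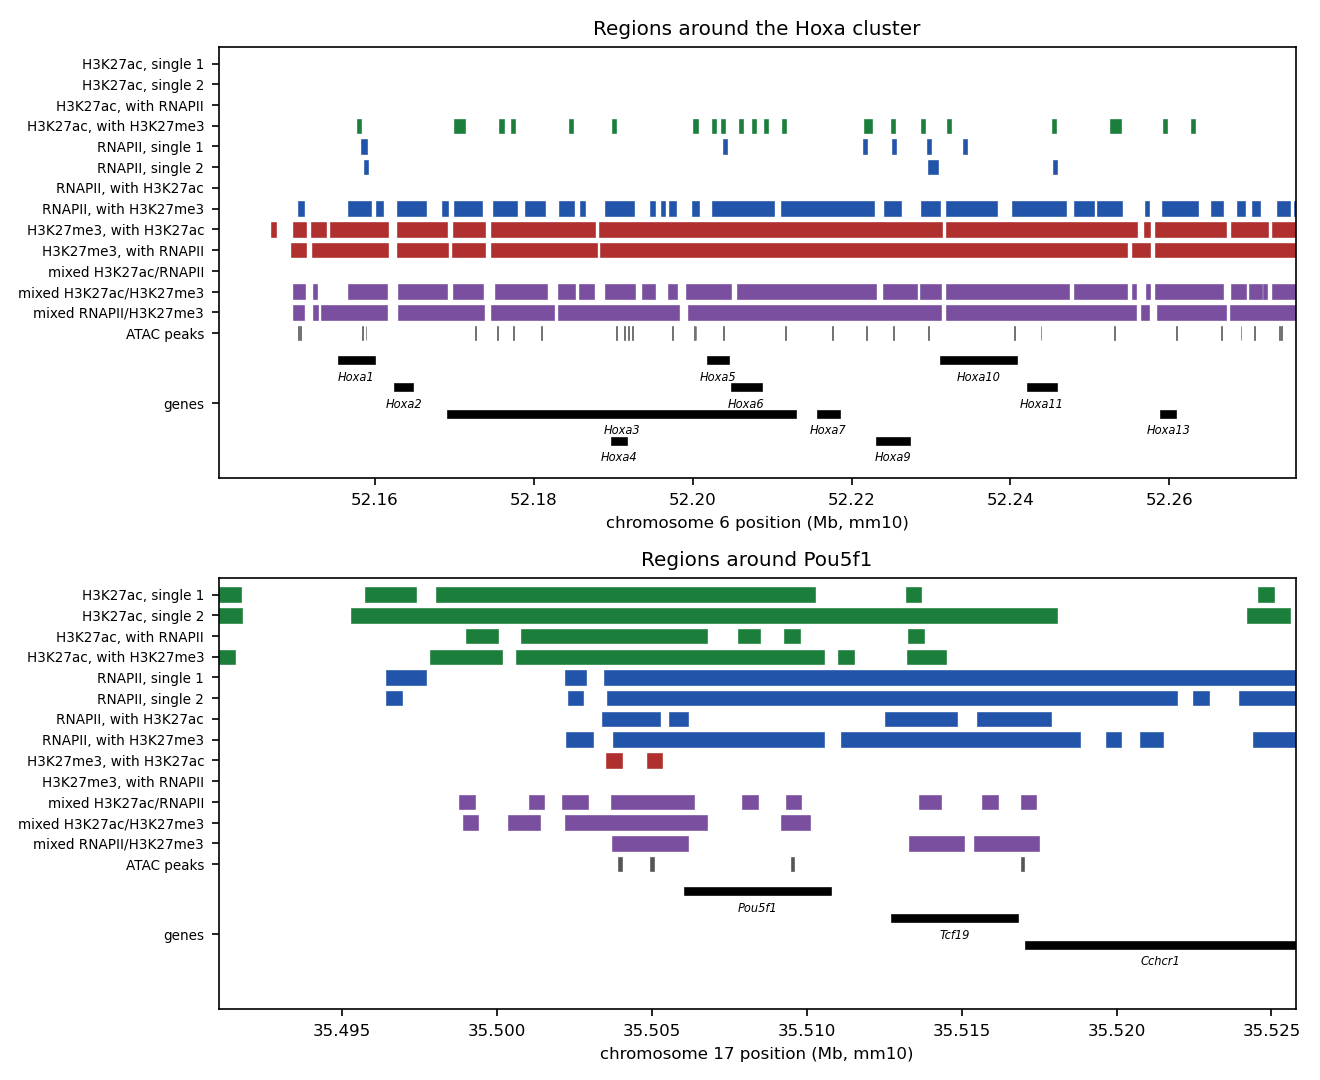
Regions of each list (vertical axis) around the Hoxa cluster on chromosome 6 and Pou5f1 on chromosome 17 (horizontal axis, position in Mb, mm10), with genes as black bars. The RNAPII/H3K27me3 experiment has 30 RNAPII regions in the Hoxa window, and no H3K27ac region of a single list lies there.

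H3K27me3 regions were split into deciles by value and compared for the presence of the other target at their centre. A region in both replicate lists had the same merged value in each, so the SDs can understate the replicate spread. In the lowest decile of H3K27me3 regions outside both single H3K27ac lists, 1.49% ± 0.367 had an H3K27ac region of the same experiment at the centre, and in the highest decile 34.6% ± 0.127 (SD, n = 2 replicate lists). For RNAPII beside H3K27me3 the shares were 7.35% ± 1.37 and 75.1% ± 0.396. As a ratio the contrast was smaller where regions in the single lists were kept: over all H3K27me3 regions the shares were 9.14% ± 0.965 and 37.8% ± 1.24 for H3K27ac and 17.8% ± 1.39 and 88.0% ± 0.219 for RNAPII. The shallower lists of the H3K27ac/RNAPII experiment covered 3.78% ± 0.184 of all regions in the lowest and 0.319% ± 0.361 in the highest decile for H3K27ac, and 2.60% ± 0.424 and 1.68% ± 0.372 for RNAPII, a comparison added after the data were seen. The share with an H3K27ac region of single replicate 2 was 13.7% ± 0.240 in the lowest decile and 6.61% ± 1.08 in the highest, and single RNAPII replicate 1 stood at 11.7% ± 0.170 and 22.4% ± 0.170. H3K27ac regions beside H3K27me3 that lay outside both H3K27me3 lists had a mixed region of the same experiment in 1.65% ± 0.720 of cases in the lowest decile by H3K27ac value and 68.8% ± 7.65 in the highest. Mixed RNAPII/H3K27me3 regions, from libraries without the H3K27ac antibody, lay at 3.32% ± 0.465 and 21.2% ± 4.23 of them.

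**Figure D4:**
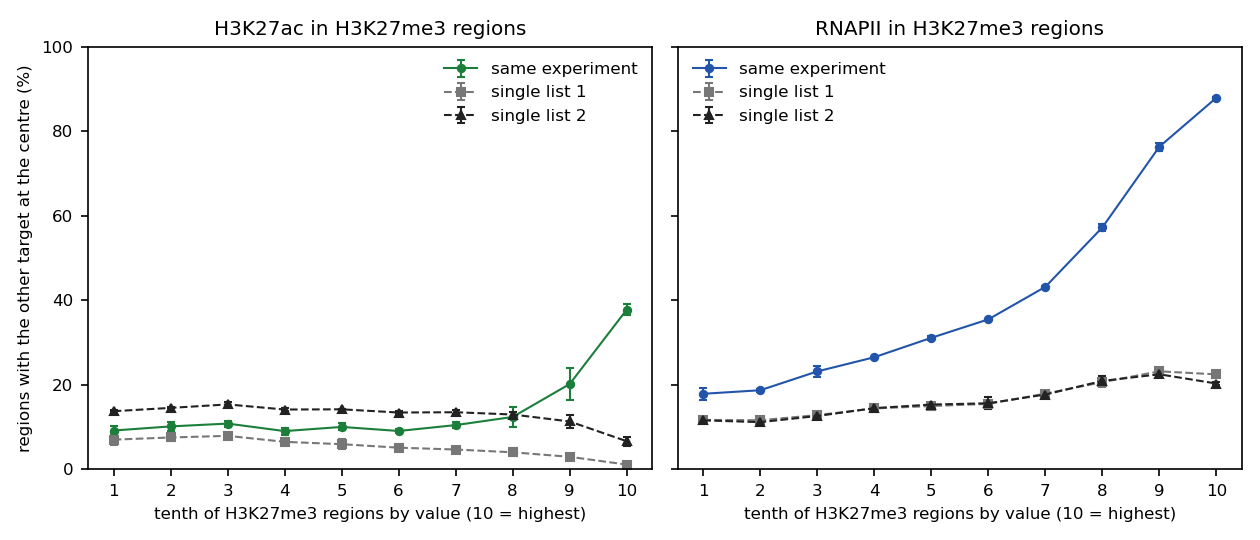
Share of H3K27me3 regions (percent, vertical axis) with a region of the other target at their centre, by decile of H3K27me3 value (horizontal axis), as the mean of 2 replicate lists with SD bars. In the highest decile the share for H3K27ac of the same experiment is 37.8%, and for RNAPII of the same experiment 88.0%.

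Genes were sorted by the regions within 1 kb of either end, to ask which genes carry an active and a repressive mark. Each target was counted separately, so the targets of a gene could lie at opposite ends. At Esrrb beside each other, H3K27ac lay at 86518359 to 86522154 on chromosome 12 and H3K27me3 at 86360767 to 86361951. Of 21631 protein-coding genes, 4635 had both H3K27ac and H3K27me3 in the merged lists of that experiment, 7718 had H3K27ac only and 2243 had H3K27me3 only. The number expected if the targets were independent was not computed. Mixed regions were found at 94.2% of the genes with both, 59.7% of those with H3K27ac only, 72.3% of those with H3K27me3 only and 2.16% of those with neither. In the RNAPII/H3K27me3 experiment 6221 genes had both targets, 98.1% of them with a mixed region, and 470 had H3K27me3 only. In the H3K27ac/RNAPII experiment 4221 genes had both, 76.6% of them with a mixed region. A total of 6080 genes had H3K27me3 in both experiments. H3K27ac was found at 54.2% ± 4.79 of these beside H3K27me3, 5.65% ± 3.45 beside RNAPII and 29.5% ± 16.1 alone, and RNAPII at 92.6% ± 0.663, 19.2% ± 1.49 and 62.3% ± 1.97 (SD, n = 2 each). Over all protein-coding genes the shares beside H3K27me3 were 50.6% ± 2.57 for H3K27ac and 70.2% ± 0.451 for RNAPII. The counts of genes with both targets depended on the lists: the 10000 highest-scoring regions gave 317, 1918 and 2925 genes for the 3 experiments in the order H3K27ac/H3K27me3, H3K27ac/RNAPII and RNAPII/H3K27me3. Regions in both replicate lists gave 2166 and 1537 for the first pair of these. A single replicate list gave as few as 2920 genes for H3K27ac with H3K27me3 (without the second list) and 2116 for H3K27ac with RNAPII (without the first).

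**Figure D5:**
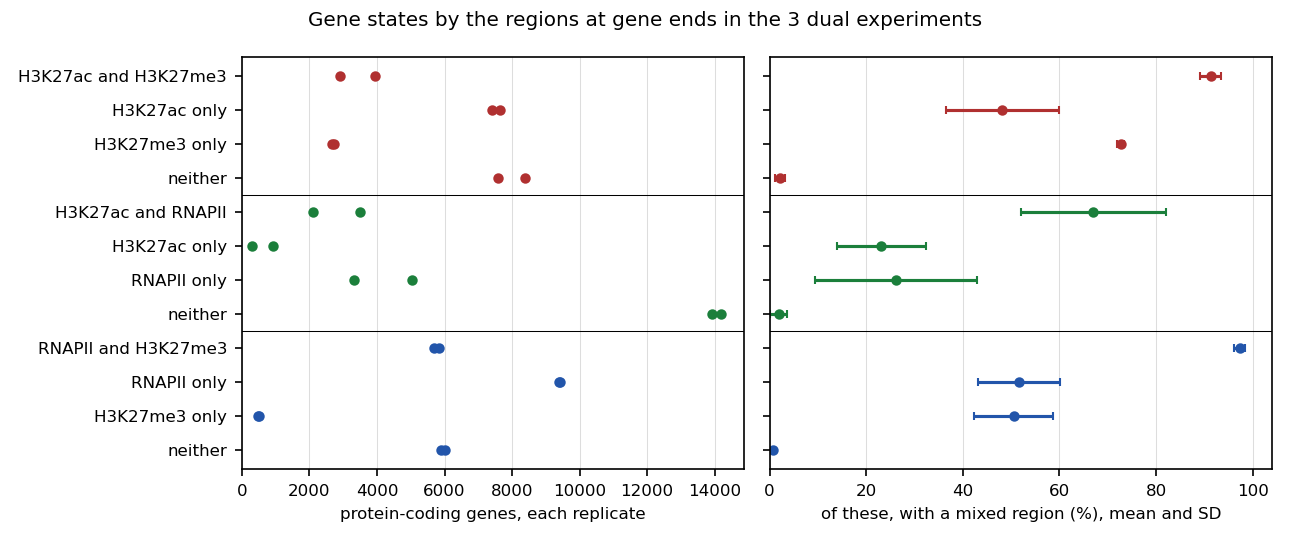
Protein-coding genes by the targets at their ends (vertical axis) in the 3 dual experiments: number of genes in each replicate (left, points) and share with a mixed region (right, percent, mean with SD of 2 replicates). Genes with both H3K27ac and H3K27me3 number 2920 and 3949 in the 2 replicates.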

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

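The tests of depth and of open chromatin at Polycomb target genes were chosen only after the result was seen, and the tests of the barcodes and both tests at housekeeping genes before. No biological explanation was tested for any of the patterns. The headers do not say how the dual-antibody lists were called, so a difference in calling from the single lists was not tested either.

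H3K27ac regions stood at 67.7% of the 79 Hox and developmental regulator genes beside H3K27me3, against 5.06% in the single lists. The tables argue against a difference in depth: the lower dual replicate, which rested on fewer tags, was above the deeper single list by 55.7 percentage points. H3K27me3-directed cuts that carry the H3K27ac barcode may contribute: outside both single H3K27ac lists the share of H3K27me3 regions with H3K27ac was 19.9 times as high in the highest as in the lowest decile, in the replicate with the lower ratio, and over all H3K27me3 regions the shares were 37.8% and 9.14%. Cutting of open chromatin without an antibody would also reach the single libraries. There H3K27ac stood at 1.64% and, in the deeper list, 9.84% of the 61 genes with an ATAC peak. The dual replicates stood at 70.5% and 75.4%. These values argue against such cutting as the cause of the whole pattern at those genes, if the lists were called alike. The ratio test left a part open. The share at the 18 genes without an ATAC peak was 0.684 of that at the 61 with one. This lay between the bounds of 0.2 and 0.8 set for the test. In the single H3K27ac lists the share over all H3K27me3 regions fell from the lowest to the highest decile. It went from 6.98% to 1.07% in replicate 1 and from 13.7% to 6.61% in replicate 2. Neither list had a region at an end of any of the 39 Hox genes. These values argue against H3K27ac at the level called in the single libraries at most of the strongest H3K27me3 regions. A weaker presence of H3K27ac at these genes stays open as untested.

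RNAPII regions stood at 100% of the same genes beside H3K27me3, against 44.9% in the single lists. Depth is argued against, with a gap of 56.96 percentage points to the deeper single list. H3K27me3-directed cuts with the RNAPII barcode may contribute. In the replicate with the lower ratio, the share with RNAPII outside the single lists rose 8.99-fold from the lowest to the highest decile. Over all H3K27me3 regions the shares were 88.0% in the highest and 17.8% in the lowest decile. Cutting of open chromatin without an antibody would also reach the single libraries. There RNAPII stood at 55.7% and 44.3% of the 61 genes with an ATAC peak. Beside H3K27me3, RNAPII stood at 100% of these and at 100% of the 18 genes without one. These values argue against such cutting as the cause of the whole pattern, if the lists were called alike. The ratio test cannot decide on a part, because all 79 genes had RNAPII. This fixes the ratio of genes without to genes with an ATAC peak at 1.0. The single RNAPII lists also covered more of the strongest H3K27me3 regions, with 22.4% and 20.3% in the highest and 11.7% and 11.5% in the lowest decile. RNAPII beside H3K27ac, from shallower lists, went the other way, with 1.68% in the highest and 2.60% in the lowest. At the 79 genes the single RNAPII lists stood below random gene lists, at 46.8% and 43.0% against means of 61.6% and 60.9%. Polymerase at these sites stays open.

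Mixed H3K27ac/H3K27me3 regions stood at 75.0% of 30 housekeeping genes, of which 11.7% carried H3K27me3. H3K27ac-directed cuts that carry both barcodes may contribute, but the decile test cannot tell. Mixed fragments are taken to carry the H3K27ac barcode too, so their share can rise with H3K27ac value under other explanations. Outside both H3K27me3 lists, the share of H3K27ac regions with a mixed region rose 34.4-fold from the lowest to the highest decile. The other replicate had a higher ratio. Mixed RNAPII/H3K27me3 regions, made without the H3K27ac antibody, also went from 3.32% to 21.2% of these regions, and which antibody directed those cuts stays open. Cutting of open chromatin without an antibody cannot be told apart from this: the share in regions without an ATAC peak was 0.708 of that in regions with one, between the bounds of 0.2 and 0.8 set for the test.

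For several gene groups both replicate lists of 1 dual experiment lay above the mean of the single lists and both of the other below it, which is why they are listed here, and the difference was not tested. For some groups 1 of the single lists lay on the other side of a dual list, as for germline, trophoblast and fibroblast genes with H3K27ac. All protein-coding genes had the same order, with H3K27ac at 50.6%, 44.7% and 15.8% and RNAPII at 70.2%, 61.3% and 32.2% beside H3K27me3, alone and in the H3K27ac/RNAPII experiment, and the differences for germline, imprinted and fibroblast genes (H3K27ac) and for differentiated tissue and pluripotency genes (RNAPII) were close to or below theirs. For H3K27ac, 6 of 11 gene groups were higher beside H3K27me3 and lower beside RNAPII than the mean of the single lists. The differences between the experiments were 78.75 percentage points for developmental regulators, 72.73 for primed pluripotency, 50 for trophoblast, 35.0 for germline, 34.78 for imprinted and 25.0 for fibroblast genes. For RNAPII, 9 of 11 groups were higher beside H3K27me3 and lower beside H3K27ac than that mean. The differences were 100.0 percentage points for Hox, 95.0 for developmental regulators, 85.0 for germline, 72.73 for primed pluripotency, 67.5 for trophoblast, 67.38 for imprinted, 50 for fibroblast, 35.0 for differentiated tissue and 24.2 for pluripotency genes. The H3K27ac/RNAPII lists were also the shallowest.

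Regions outside the autosomes and X are listed here because no main comparison used them, and the difference was not tested. Among the antibody lists the mitochondrial genome held up to 5 regions, in H3K27ac replicate 1, chromosome Y up to 54, in RNAPII replicate 2, and unplaced scaffolds up to 37, in H3K27ac beside H3K27me3.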

How the results depend on the processing

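The settings that used regions in both replicate lists, the merged lists, or a single replicate list of a dual experiment were chosen after seeing the data, and the others before. Of 183 alternative values for 25 overlap results, 173 kept their direction and their side of 0.05, and the 10 that did not all asked for 50% of a region to lie in ATAC peaks. That rule gave a fold of 0 for both H3K27me3 lists, both mixed lists with H3K27me3, RNAPII beside H3K27ac, H3K27ac replicate 2 and RNAPII replicate 2, and folds of 20.0, 8.33 and 6.25 at p of 0.059, 0.13 and 0.15 for H3K27ac beside H3K27me3, RNAPII beside H3K27me3 and RNAPII replicate 1. The cause is the width of the ATAC peaks, 110 bp against regions of 500 bp or more. Leaving out a replicate list of each dual experiment gave folds from 3.78 to 87.2. The 50% rule gave no value for H3K27ac beside RNAPII in ATAC peaks, as no placement was covered. Replicate overlap of single lists has no value without a replicate, since 1 list is left. No paired analysis was possible because the comparisons between groups come from no test, so that there was no fit to which the replicate number could be added as a block.

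Of 99 alternative values for 15 shares of genes, 76 stayed within 1 SD between replicates of the main value and 23 did not, and except for the window the cause was not tested. Leaving out a replicate list stayed within that SD by construction, but small shares differed several times over: H3K27ac alone at the 79 genes was 1.27% to 8.86% and H3K27ac beside RNAPII 0% to 3.80%. For the 79 Hox and developmental regulator genes, the 10000 highest-scoring regions gave 12.0% for H3K27ac and 81.0% for RNAPII beside H3K27me3, 0% for RNAPII beside H3K27ac and 1.27% for RNAPII alone. They gave 48.3% and 55.0% for mixed regions with H3K27ac and with RNAPII at housekeeping genes, 3.33% for H3K27me3 there in both experiments, and for H3K27ac at pluripotency genes 83.9% beside H3K27me3 and 71.0% alone. Regions in both replicate lists gave 46.8% for H3K27ac and 0% for RNAPII beside H3K27ac at the 79 genes, and 3.33% for H3K27me3 beside H3K27ac at housekeeping genes. Merged lists gave 86.1%, 5.06% and 16.7% for the same results. A window of 2.5 kb gave 77.9% for H3K27ac beside H3K27me3, 5.06% for RNAPII beside H3K27ac and 55.7% for RNAPII alone at the 79 genes. Whole genes gave 81.7%, 6.96% and 60.1%, and 77.4% for H3K27ac beside RNAPII at pluripotency genes. Each of these rises with the window by construction.

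Of 14 percentiles 6 stayed the same. Percentiles against random lists of genes with an ATAC peak were 99.96 for H3K27ac and 99.83 for RNAPII beside H3K27me3 at the 79 genes, 0.005 and 0 for the single RNAPII lists, 98.8 and 99.4 for mixed regions at housekeeping genes, and 1.125 and 0.09 for H3K27me3 there. Of 15 alternative counts of genes with both targets 8 stayed within 1.5 times the main count. The counts were 317, 1918 and 2925 with the 10000 highest-scoring regions (H3K27ac/H3K27me3, H3K27ac/RNAPII, RNAPII/H3K27me3). They were 2166 and 1537 for the first pair of these with regions in both replicate lists, and 2920 to 3949 and 2116 to 3486 with a single replicate list. Shares at gene ends were 28.3%, 33.5%, 41.9% and 22.0% within 2.5 kb and 32.0%, 31.7%, 44.3% and 23.3% in the higher-scoring part, for H3K27me3 beside H3K27ac, RNAPII beside H3K27ac, mixed RNAPII/H3K27me3 and H3K27ac replicate 2. Depth limits the H3K27ac/RNAPII lists most, and a region missing there is not shown to be absent.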

Other observations

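Of the imprinted genes, Grb10, Cdkn1c and Dlk1 each had both H3K27ac and H3K27me3 in the dual lists. These lists do not separate parental alleles, and either gene end counted, so the targets need not lie together. At Grb10 the H3K27me3 region beside H3K27ac ran over 38.1 kb of chromosome 11 (12012647 to 12050770, mm10) and at Cdkn1c, an inhibitor of the cell cycle, the region beside RNAPII ran over 56.4 kb of chromosome 7 (143411663 to 143468075). H3K27ac stood at 37.0% ± 3.07 of 23 imprinted genes beside H3K27me3, 2.17% ± 3.07 beside RNAPII and 23.9% ± 9.22 alone. RNAPII stood at 91.3% of 23 imprinted genes beside H3K27me3, 23.9% ± 3.07 beside H3K27ac and 76.1% ± 3.07 alone (SD, n = 2 each).

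Among trophoblast genes, of which 6 of 20 had no H3K27me3 at an end, Gata2 carried H3K27me3 regions of 19.8 kb and 19.9 kb with values of 5906 and 6279 tags per 10000000, and Cdx2, which directs the trophectoderm, carried regions of 25.1 kb and 32.0 kb with values of 3029 and 5212. Bmp4 had the highest H3K27ac value of the group beside H3K27me3, at 265.9. RNAPII beside H3K27me3 was highest within the group at Gata2 (725.7) and Tfap2c (605.8).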
